A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

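Total RNA of a budding yeast strain that lacks SSE1 was measured on 6 arrays. Per the labels, 3 arrays came from cells with an empty plasmid and 3 from cells with a multi-copy plasmid for yEVenus, a yellow fluorescent protein adapted to yeast codon use. The replicates of each group were grown from independent colonies in medium without leucine to the exponential phase, and RNA was extracted with Trizol. Biotin-labelled cRNA was made with the manufacturer's kit that primes at the 3' end of transcripts and was hybridised to Affymetrix expression arrays, per the labels' protocols.

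The deposited values are log2 expression levels, 1 per probe set and array. RMA and R 3.2.0 are named in the submitters' processing notes. The labels give no batch or date of labelling or hybridisation. RMA corrects background, makes the distributions of the arrays equal and summarises the probes of a set, so every difference below is relative to the bulk of the transcripts on the array. A change of all transcripts by the same factor would not show in the differences between genes. The genome build and any filter are not given in the sources used here. The array medians of the deposited log2 values lay between 9.06 and 9.13.

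The table holds 5900 probe sets. Of these, 5498 name 1 gene in the platform annotation, 0 name several and 402 name none, among them 137 control probe sets. Names were updated through the gene identifiers of a RefSeq gene table of assembly R64, which changed 12 symbols. That table also gave the chromosome, gene order and length of each gene. Its coordinates are not printed because no build is named for the files. Gene lengths were multiples of 3 in 97% of genes and are called coding lengths; introns are included where a gene has them. Where a gene had more than 1 probe set, as 47 genes did, the brightest over all 6 arrays was used, leaving 5449 genes.

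The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, 4 residual degrees of freedom, no block). P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Differences are yEVenus plasmid minus empty plasmid. "Rose" and "fell" are used for genes past that threshold. The number of arrays limits the precision: an exact two-sided permutation test of 3 arrays against 3 cannot go below 0.1, so single values carry the moderated limma test.

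Gene lists were written before the data were examined, from textbook knowledge of yeast pathways, complexes, stress responses and cell types. Of 43 lists, 42 had at least 3 measured members; the genes of the native 2-micron plasmid had 0 measured members and were not tested. Camera was run on each list with a preset inter-gene correlation of 0.01 and the same adjustment over lists, and again with an estimated correlation. Camera asks whether the genes of a list moved relative to the other genes. Fry, which asks whether the genes of a list moved one way on balance, was an alternative. Each of 16 chromosomes was tested as a set in the same manner.

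Named genes were chosen by a rule fixed at the same time. It took SSE1 and LEU2, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, and up to 3 members with the smallest p in the direction of each list past the threshold. For 6 lists on protein folding, degradation, stress and ribosomes, the 2 members with the smallest p were added whatever the result.

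Other settings, fixed at the same time, were cyclic loess, median centring and quantile normalization of the genes tested, leaving out the dimmest genes by mean level, testing every probe set, averaging the probe sets of a gene, other variance models, array weights, the replicate number as a block, a minimum change of 1.2-fold, other thresholds and leaving out each array. Leaving out the dimmest genes replaced a filter on the probe sets of another species, which the table used here did not let apart from the rest. The alternative that compares further probe sets of SSE1 and LEU2 could not be run, as each has 1. After the data were seen, 3 alternatives were added. The first removed from each array a loess trend (span 0.5) of the deviation from the gene mean on log2 coding length. The second left out the genes of chromosomes I and II, and the third did both.

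The gene test was checked on simulated arrays made from the means and residual spread of the 5449 genes, with 66 or 67 genes changed at each size. It recovered 40.3% of the genes changed by 1.2-fold, 86.6% at 1.5-fold and 100% at 2-fold, and 6.8% of its calls were false. These arrays had independent noise, few changed genes and no length trend, so the 6.8% does not carry over to the real comparison. In simulated arrays with a known length trend, removal took the Spearman rho from -0.87 to 0.02.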

Results

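Expression was compared between cells with a multi-copy plasmid for yEVenus, a fluorescent protein with no role in yeast, and cells with an empty plasmid. Both were in a strain without SSE1, and no value here measures yEVenus itself. Sse1 is an Hsp110 protein that serves as a nucleotide exchange factor for cytosolic Hsp70, and its loss was chosen by the study as a sensitised background. The question was which genes respond to the yEVenus plasmid, which is meant to overproduce the protein. Each group had 3 arrays from independent colonies. Across the 5449 genes, arrays of the same group correlated at 0.996 to 0.998 and arrays of different groups at 0.966 to 0.978. The SD of the log2 difference between pairs of arrays was 0.12 to 0.20 within groups and 0.45 to 0.56 between them.

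The deleted gene was at the floor in all samples. SSE1 (YPL106C) had a log2 level of 3.14 ± 0.116 with the empty plasmid and 3.17 ± 0.071 with yEVenus (SD, n = 3 each), close to the 3.03 and 3.19 of control probe sets that have no target. Its difference of 0.03 did not pass the limma test (adjusted p = 0.766). LEU2 (YCL018W), which encodes an enzyme of leucine synthesis and complements growth without leucine, was among the bright genes in both groups. It fell from 13.82 ± 0.004 to 12.97 ± 0.026 (SD, n = 3 each), a log2 difference of -0.85 ± 0.0454 (SE; limma, adjusted p = 6.58e-06). The labels do not state the plasmids' marker gene.

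The 10 largest rises with yEVenus were in genes of different functions. CWP1 (YKL096W), a cell wall mannoprotein, rose from 8.68 ± 0.103 to 11.26 ± 0.101, which is 5.97-fold. AGA2, the binding subunit of a-agglutinin, rose 3.85-fold, and MET2, which encodes homoserine O-acetyltransferase, rose 4.23-fold. SIP18, a desiccation-related hydrophilin, rose 6.33-fold, and SPG1, a gene named for its role in stationary phase, rose 5.68-fold. In the empty-plasmid group these last genes varied more between colonies than the other 8 of the 10 largest rises, with an SD of 0.887 for SIP18 and 0.552 for SPG1. RTP1 (YMR185W), required for nuclear import of RNA polymerase II, rose 5.75-fold from 9.02 ± 0.063 to 11.54 ± 0.064 (SD, n = 3 each). The glutaredoxin gene GRX8 rose by 2.05 on the log2 scale. The remaining genes of the 10 were the little-characterised YNL146C-A, YGL230C and YER053C-A, with log2 differences of 2.26, 2.06 and 2.03. Several of the 10 are short, and with the length trend removed the log2 difference was 1.26 for YER053C-A (114 nt), 1.57 for YNL146C-A (195 nt), 2.03 for SIP18 (240 nt), 1.34 for AGA2 (264 nt), 1.93 for SPG1 (288 nt), 1.53 for GRX8 (330 nt) and 1.67 for YGL230C (444 nt). It was 2.46 for CWP1, 2.24 for MET2 and 2.78 for RTP1. The largest adjusted p among the 10 in limma was 4.49e-04, for SIP18.

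The 10 largest falls included several regulators. NUT2, a Mediator subunit, had a log2 difference of -2.06, going from 6.17 ± 0.62 to 4.11 ± 0.294 (SD, n = 3 each). PHO4, the activator of the phosphate regulon, fell from 9.77 ± 0.472 to 7.86 ± 0.077, and YAP7, a bZIP transcription factor, from 6.83 ± 0.278 to 4.87 ± 0.23. The vacuolar SNARE gene VAM7 had a log2 difference of -1.99, CMR1 one of -1.75 and ESC2, a genome maintenance gene, one of -1.66. SWH1, an oxysterol-binding protein gene on chromosome I, was at -1.66. YAR010C and YHL009W-B, which belong to Ty retrotransposons, were at -2.28 and -1.65, and YBL111C, part of a subtelomeric Y' element, was at -2.20. The probe sets of these last 3 can read several near-identical copies, so the values stand for families. The largest adjusted p of the 10 in limma was 9.11e-04, for YBL111C.

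**Figure D1:**
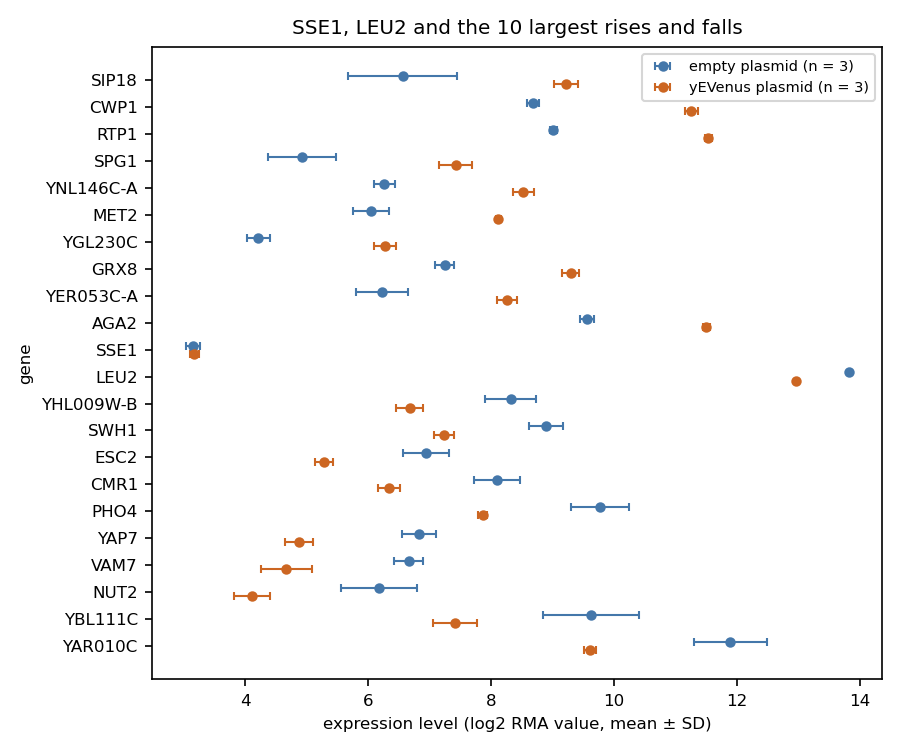
Log2 expression level (x axis, mean ± SD, n = 3 arrays per group) of SSE1, LEU2 and the 10 genes with the largest rises and falls (y axis). SSE1 lies near 3.1 in both groups, while RTP1 goes from 9.02 to 11.54 and NUT2 from 6.17 to 4.11.

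In all, 3835 of 5449 genes changed, 1599 upward and 2236 downward, which is 70.4% of genes. The excess of falls depended on the scaling: median centring gave 1846 rises and 1858 falls, and cyclic loess 1787 and 1897. Most changes were small: the median absolute log2 difference over all genes was 0.30, and 190 genes rose and 71 fell by 2-fold or more. The groups did not overlap for 74.9% of genes, where chance gives 10%. Direction followed coding length. Of genes up to 300 nt long, 70.8% rose and 5.8% fell, with a median log2 difference of 0.57; of genes over 3600 nt, 2.8% rose and 69.3% fell, with a median of -0.28. Across genes, which are not independent replicates, Spearman's rho of log2 difference and coding length was -0.46. With the length trend removed, 3533 genes changed, 1728 upward and 1805 downward, and 2677 genes were called in both fits with the same direction. Against a minimum change of 1.2-fold, 1753 genes changed.

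**Figure D2:**
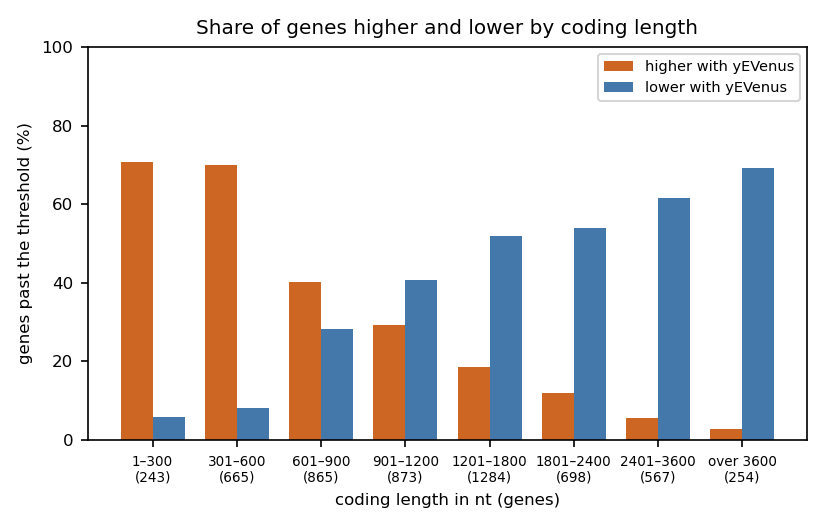
Percent of genes (y axis) that were higher or lower with yEVenus at an adjusted p under 0.05, by coding length in nt (x axis, number of genes in brackets). The share of higher genes goes from 70.8% in the shortest class to 2.8% in the longest, and the share of lower genes from 5.8% to 69.3%.

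Control probe sets differed between the groups too. The arrays carry 3' and 5' probe sets for 7 yeast genes, and the 3' minus 5' gap was larger on every yEVenus array than on every empty-plasmid array for 7 of the 7. The mean gap was 1.83 ± 0.029 with the empty plasmid and 2.48 ± 0.067 with yEVenus (SD of array means, n = 3 each). The 3' probe sets differed by 0.05 on average and the 5' probe sets by -0.60. By gene, the 3' difference ran from -0.11 (SPT15) to 0.41 (TDH1) and the 5' difference from -1.10 (EAF5) to -0.045 (TDH1). TDH1 thus differed mainly at its 3' probe set, and RIP1 at both, with 0.30 and -0.22. For ACT1, which changed least of the 7, the gap went from 0.66 to 1.04. For EAF5, which changed most, it went from 1.93 to 2.95, with the 3' probe set at -0.07 and the 5' probe set at -1.10. The median coding length is given beside each list that passed.

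**Figure D3:**
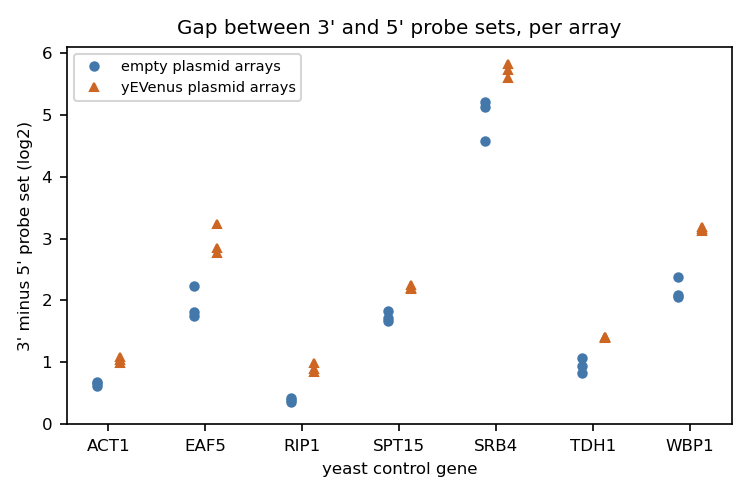
Log2 difference between the 3' and 5' probe set (y axis) of 7 yeast control genes (x axis), 1 point per array. For ACT1, with the smallest change, the empty-plasmid arrays average 0.66 and the yEVenus arrays 1.04. For EAF5, with the largest, they average 1.93 and 2.95. The groups do not overlap for any of the 7 genes.

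Ribosome biogenesis, aminoacyl-tRNA synthetases and translation factors fell. In ribosome biogenesis, 81 of 91 measured genes fell and 3 rose, with a median log2 difference of -0.50 (camera, adjusted p = 1.15e-09; median coding length 1668 nt). MAK16, on chromosome I, had a log2 difference of -1.16, RRP36 one of -0.88 and KRR1 one of -0.70. Of the cytosolic aminoacyl-tRNA synthetases, 19 of 19 fell (median -0.37, adjusted p = 2.01e-04; 1824 nt), with SES1 at -0.56, WRS1 at -0.55 and KRS1 at -0.53. Of 34 translation factors, 29 fell and 3 rose (median -0.36, adjusted p = 7.28e-04; 1312.5 nt); TIF3, which encodes eIF4B, was at -0.88, TIF4631, an eIF4G gene, at -0.71 and EFB1, on chromosome I, at -0.54. These 3 lists stayed past the threshold with the length trend removed, with adjusted p of 2.65e-08, 0.00299 and 1.61e-04; KRS1 was then at -0.34 and TIF4631 at -0.47. With an estimated correlation, the adjusted p of each of the 3 was 0.544.

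Proteasome genes fell as well, 27 of 33 with 1 rise and a median of -0.35 (camera, adjusted p = 3.95e-04; 867 nt). RPN8 and RPN5 of the lid were at -0.79 and -0.75, and RPT1, an ATPase of the base, at -0.58. The call stayed with the length trend removed (adjusted p = 8.86e-06, median -0.36). With an estimated correlation, the adjusted p was 0.544.

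The cytosolic Hsp70 and Hsp90 lists were lower with yEVenus, near the threshold. In the cytosolic Hsp70 system, 12 of 18 genes fell and 1 rose (median -0.26, camera, adjusted p = 0.0385; 1695 nt). SSE2, the paralogue of the deleted gene, which lies on chromosome II, fell from 10.30 ± 0.181 to 9.45 ± 0.103 (SD, n = 3 each), and the J-domain gene CAJ1 and the ribosome-associated Hsp70 gene SSZ1 were at -0.59 and -0.58. Of 12 Hsp90 and co-chaperone genes, 8 fell and 1 rose (median -0.31, adjusted p = 0.041; 1185 nt); CNS1, on chromosome II, was at -1.13, CPR7 at -0.54 and SBA1, the p23 homologue, at -0.50. Neither call was robust: without the length trend the medians were -0.14 and -0.15 and the adjusted p 0.131 and 0.0826. The medians moved little without chromosomes I and II (-0.24 and -0.29, adjusted p = 0.0557 and 0.0607) and without the dimmest genes (-0.27 and -0.31, adjusted p = 0.0573 and 0.0648). With an estimated correlation the adjusted p was 0.544 for both. Leaving out empty-plasmid replicate 3 gave 0.0717 and 0.0522, and leaving out replicate 1 gave 0.0556 for the Hsp90 list.

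The targets of the heat shock factor Hsf1 did not pass as a list (median -0.26, camera, adjusted p = 0.0865), although 15 of 25 fell and 2 rose; without empty-plasmid replicate 2 the adjusted p was 0.027. HSP10, the mitochondrial co-chaperonin gene, rose by 0.40, which turned to -0.13 with the length trend removed (coding length 321 nt). Of 21 unfolded protein response genes, 7 fell and 5 rose (adjusted p = 0.932). PMT2, an O-mannosyltransferase gene on chromosome I, was at -0.76 and FPR2, an endoplasmic reticulum prolyl isomerase gene, rose by 0.55, or 0.13 with the length trend removed (408 nt). In chaperonin and prefoldin, 10 of 15 fell and 4 rose (adjusted p = 0.332), and the list passed at 0.0236 with the length trend removed. Ubiquitin and protein quality control had 11 falls and 3 rises among 23 genes (adjusted p = 0.439).

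Sulfur and nitrogen metabolism moved upward. In sulfur and methionine, 19 of 25 genes rose and 5 fell, with a median of 0.57 (camera, adjusted p = 2.04e-04; 1461 nt). The sulfate permease gene SUL1 rose 2.88-fold, the adenylylsulfate kinase gene MET14 2.66-fold and the regulator gene MET28 2.63-fold. MET17 is also among the 19. Its log2 levels, 3.19 with the empty plasmid and 3.47 with yEVenus, lay near those of probe sets with no target. Of 28 genes under nitrogen catabolite repression, 18 rose and 5 fell (median 0.28, adjusted p = 0.00185; 1648.5 nt). CAR2, of arginine breakdown, rose 2.18-fold, the repressor gene DAL80 1.78-fold, and the allantoin permease gene DAL4 went from 5.88 ± 0.044 to 6.88 ± 0.098 (SD, n = 3 each). In hexose transport, 7 of 14 rose and 1 fell (median 0.24, adjusted p = 0.0256; 1711.5 nt), with HXT4 at 2.96-fold, HXT2 at 1.71-fold and GAL2 at 1.58-fold. With the length trend removed, the adjusted p of these 3 lists was 4.98e-05, 4.98e-05 and 0.00326, and with an estimated correlation it was 0.544 for each. The removal moved their medians up to 0.79, 0.41 and 0.43. It raises long genes near background too, as the deleted SSE1 (2082 nt) went from 0.03 to 0.23. The adjusted p with the length trend removed may in part reflect that shift. Without the dimmest genes, the nitrogen and hexose lists had medians of 0.18 and 0.58 and adjusted p of 0.0526 and 0.0767. Under cyclic loess the hexose list had a median of 0.26 and an adjusted p of 0.0606.

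Amino acid synthesis under Gcn4 went the other way: 28 of 42 genes fell and 4 rose (median -0.24, camera, adjusted p = 0.00526; 1267.5 nt), or 28 and 5 adjusted over the list alone. SER3 was at -0.98, GLN1 at -0.61 and CPA1 at -0.52. The call ended with the length trend removed (adjusted p = 0.124, median -0.10) and with an estimated correlation (adjusted p = 0.544). Of the 7 genes of the leucine synthesis list, 1 rose (adjusted p = 0.82), with a median of 0.01 and a mean of -0.002. LEU2, which fell by 0.85, is not a member of that list.

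Markers of stationary phase rose, 10 of 13 with 0 falls and a median of 1.04 (camera, adjusted p = 7.28e-04; 507 nt). SNO1, of vitamin B6 metabolism, rose 3.81-fold, RTC3 1.86-fold and SPG5 1.55-fold; SIP18 and SPG1, named above, are members too. With the length trend removed the median was 0.75, RTC3 (336 nt) went from 0.90 to 0.39 on the log2 scale and the adjusted p was 0.0236; with an estimated correlation it was 0.544. General stress genes under Msn2 and Msn4 were mixed, with 15 of 31 rising and 4 falling (median 0.18, adjusted p = 0.0444; 786 nt). RIM4, an RNA-binding protein gene of meiosis, rose 1.84-fold, TFS1, an inhibitor of carboxypeptidase Y, 1.75-fold and GPX1, a peroxidase gene, 1.59-fold, while YGP1, a secreted glycoprotein gene, fell by 0.63. GPX1 (504 nt) went from 0.67 to 0.35 on removal of the length trend. The list's call was lost with the length trend removed (adjusted p = 0.425), an estimated correlation (adjusted p = 0.544), cyclic loess (0.0606), the dimmest genes left out (0.164), every probe set (0.0681) and array weights (0.0524). It was also lost without empty-plasmid replicate 1 (0.0955) and without yEVenus replicate 1 (0.1). The list's median was 0.08 with the length trend removed and 0.09 without the dimmest genes. It was 0.21 under cyclic loess, 0.18 with every probe set and 0.17 with array weights. Without those replicates it was 0.16 and 0.13.

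Several lists of short genes rose, and their calls as lists ended with the length trend removed. Of 35 respiratory chain genes, 24 rose and 6 fell (median 0.47, camera, adjusted p = 4.41e-05; 462 nt), led by the cytochrome c isoform gene CYC7 at 3.75-fold, COX7 at 2.27-fold and ATP20 at 1.88-fold. Mitochondrial ribosomal proteins had 37 rises and 16 falls among 69 genes (median 0.26, adjusted p = 0.00322; 699 nt), with MRPL32 at 0.99, RSM19 at 0.94 and MRPL39 at 0.83 on the log2 scale. Cytosolic ribosomal proteins had 49 rises and 18 falls among 127 (median 0.09, adjusted p = 0.0036; 771 nt), or 47 and 18 adjusted over the list alone; RPS9A rose 2.15-fold, RPS14B 1.55-fold and RPS22B 1.45-fold. Of 9 histone genes, 6 rose (median 0.21, adjusted p = 0.0232; 399 nt), HTA1 by 0.71, HTB1 by 0.35 and HHT2 by 0.21; with the length trend removed they were at 0.28, -0.088 and -0.21. Removal also took COX7 (183 nt) from 1.18 to 0.48, ATP20 (348 nt) from 0.91 to 0.42, MRPL39 (213 nt) to 0.17 and RSM19 (276 nt) to 0.35. Without the length trend the adjusted p of the 4 lists was 0.124, 0.402, 0.161 and 0.124, and the medians were 0.09, 0.04, -0.03 and -0.21, so that both the cytosolic ribosomal and the histone list turned in direction, with 24 rises and 52 falls in the former and 1 rise and 6 falls in the latter. The coding lengths include introns, so a gene with an intron was treated as longer than its coding sequence when the trend was removed. The values of the cytosolic ribosomal list with the length trend removed depend on these lengths. Removal with introns left out was not tested. With an estimated correlation the adjusted p of the 4 lists was 0.544, 0.544, 0.63 and 0.544.

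Cell cycle and mating type genes were also scored. In mitosis and early G1, 13 of 20 genes fell and 2 rose (median -0.38, camera, adjusted p = 0.0256; 1705.5 nt), with BUD4 at -0.75, the anaphase activator gene CDC20 at -0.74 and the polo kinase gene CDC5 at -0.69. Of 7 a-specific genes, 5 rose and 1 fell (median 0.71, adjusted p = 0.0256; 630 nt); the a-factor gene MFA1 rose by 1.72 on the log2 scale and ASG7 1.71-fold, beside AGA2. With the length trend removed MFA1 (111 nt) was at 0.95 and BUD4 (4344 nt) at -0.45. The medians of the mitosis and a-specific lists were then -0.22 and 0.58, with adjusted p of 0.126 and 0.0735. With an estimated correlation the adjusted p was 0.544 for each. Without the dimmest genes the a-specific list had a median of 0.56 and an adjusted p of 0.0582. Alpha-specific genes, markers of the other mating type, had 3 rises and 1 fall among 4 (adjusted p = 0.408). Haploid-specific and pheromone genes had 8 rises and 6 falls among 20 (adjusted p = 0.251), and meiosis and sporulation genes 7 and 6 among 22 (adjusted p = 0.389).

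**Figure D4:**
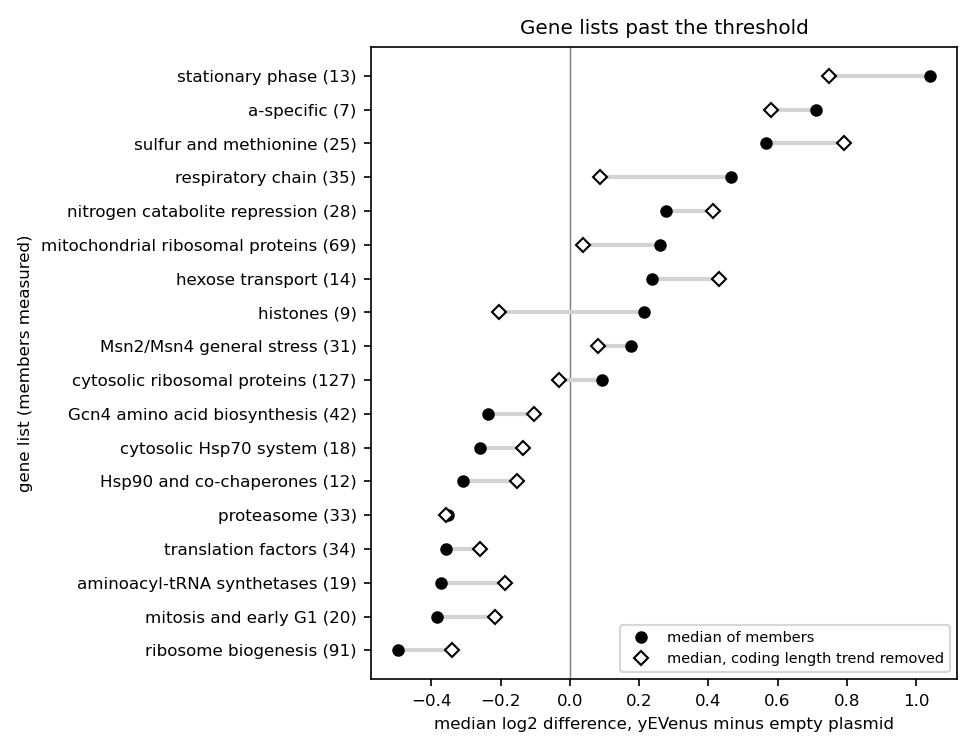
Median log2 difference, yEVenus minus empty plasmid (x axis), of the members of each of the 18 gene lists past the threshold (y axis, number of measured members in brackets). Filled circles are the deposited values and open diamonds the values with the coding length trend removed; the median of histones goes from 0.21 to -0.21 and that of the proteasome from -0.35 to -0.36.

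The other lists did not pass in camera. The iron regulon had 9 rises and 3 falls among 21 genes (adjusted p = 0.0515), or 8 and 2 adjusted over the list alone, and it passed at 0.0236 with the length trend removed, at 0.0452 with median centring, at 0.0472 with array weights, at 0.0429 without chromosomes I and II and at 0.0417 without empty-plasmid replicate 1. Removal of the length trend moved its median (1587 nt) from 0.15 to 0.28, a shift that long genes near background also show. RNA polymerase I and III had 14 falls and 6 rises among 23 (adjusted p = 0.203), passing at 0.0368 with the length trend removed. Zinc and copper genes had 7 rises and 3 falls among 12 (adjusted p = 0.0865), oxidative stress genes 12 and 5 among 25 (0.186), or 11 and 5 adjusted over the list alone, and cell wall genes 7 and 6 among 24 (0.341). Phosphate starvation had 5 rises and 4 falls among 15 (0.424), or 4 and 4 adjusted over the list alone, and autophagy and vacuole 7 and 6 among 20 (0.424). Falls outnumbered rises in glycolysis and fermentation, with 10 and 2 among 23 (0.223), multidrug resistance, with 7 and 2 among 13 (0.251), and the TCA cycle, with 12 and 5 among 24 (0.439). DNA damage had 4 falls and 2 rises among 11 (0.439), ergosterol 8 and 6 among 24 (0.601), and inositol and phospholipid 8 and 4 among 15 (0.64). Trehalose and glycogen had 9 falls and 3 rises among 18 (0.682), mitochondrial chaperones and import 9 and 5 among 18 (0.738), and G1 and S phase 8 and 4 among 24 (0.98), the last with a median of 0.01 and a mean of -0.01. In 37 of the 42 lists, the counts adjusted over the list alone were those over all genes. In total 18 lists passed, 10 upward and 8 downward; 0 passed with an estimated correlation and 37 with fry, which does not compare a list with other genes.

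Genes of chromosomes I and II were lower on the yEVenus arrays. On chromosome I, 57 of 90 genes fell and 14 rose, with a median log2 difference of -0.44 (camera, adjusted p = 0.00294). On chromosome II, 234 of 387 fell and 71 rose, with a median of -0.32 (adjusted p = 4.12e-04). The medians of the other 14 chromosomes lay between -0.12 and 0.02. Against the mean of the empty-plasmid arrays, the yEVenus replicates had medians of -0.42, -0.39 and -0.47 for chromosome I and of -0.29, -0.33 and -0.33 for chromosome II. With the length trend removed the medians were -0.38 and -0.24, and neither chromosome passed with an estimated correlation (adjusted p = 0.246 and 0.303).

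**Figure D5:**
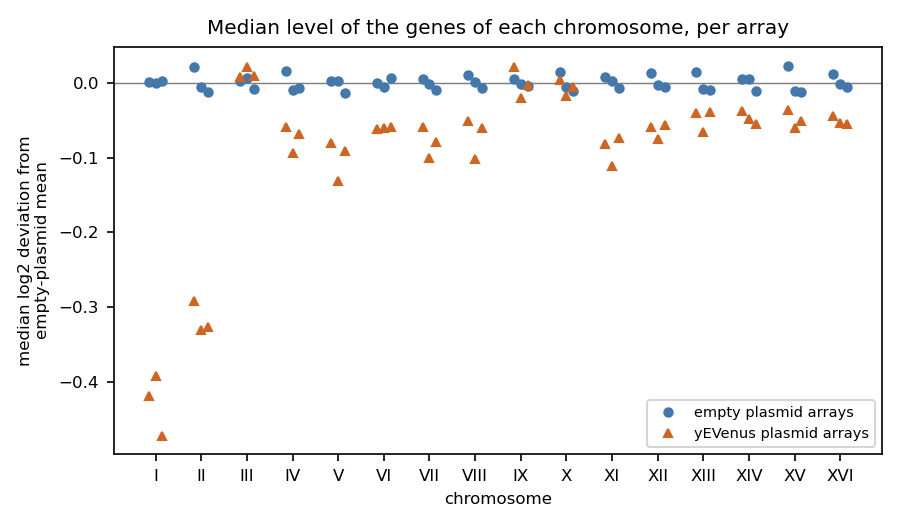
Median log2 deviation of the genes of each chromosome from the mean of the empty-plasmid arrays (y axis), for the 16 chromosomes (x axis), 1 point per array. The yEVenus arrays lie between -0.47 and -0.39 for chromosome I and between -0.33 and -0.29 for chromosome II.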

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

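The tests of other splits of the arrays were set before the result was seen; the tests on control probe sets, matched gene sets, windows of neighbouring genes and RTP1 were chosen only after it.

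Several kinds of probe set outside the gene comparison differed between the groups. The poly-A spike-ins, bacterial transcripts added to the RNA during preparation, were higher on the yEVenus arrays by 1.58 on the log2 scale, from 5.36 ± 0.448 to 6.94 ± 0.254 (SD of array means, n = 3 each). The hybridisation controls, which are added already labelled, were higher by 0.49, and their own 3' minus 5' gap changed by -0.04. The 17 ribosomal RNA controls overlapped between the groups, at 9.627 ± 0.781 with the empty plasmid and 9.315 ± 0.216 with yEVenus (SD of array means, n = 3 each). The 3' minus 5' gap of the 7 yeast control genes was larger by 0.65, and that of the poly-A spike-ins by 0.64. Of 265 probe sets without a gene name, 181 changed, 113 upward and 68 downward.

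The first pattern is the large number of changed genes with shorter ones higher and longer ones lower. If transcript abundance alone were at work, both ends of a control transcript would move alike, but in 7 of 7 control genes the gap separated the groups, which argues against it for these genes. A difference in RNA integrity or in the length of the labelled product could give the mean rise of 0.65 in that gap. The gap of the poly-A spike-ins, which do not come from the cells, was larger by 0.64. That of the hybridisation controls, added already labelled, changed by -0.04. Loss of integrity in the cells' RNA before the spike-ins were added would not widen the spike-in gap. The spike-ins were dim with the empty plasmid (mean 5.36), which limits what their gap can show, so the source was not settled. After removal of the length trend 3533 genes changed, but coding length stands in for the distance of the probes from the 3' end, which was not available, so what remains may still hold part of such an effect. Separate preparation of the groups cannot be told apart from the plasmid: the spike-ins differed by 1.58 with no overlap, and the labels give no batch. An effect of overproduction on transcripts stays open, as does a lower share of mRNA in the total RNA, which would also raise the spike-ins and was not tested. The ribosomal RNA controls differed by -0.31, less than their SD of 0.781 with the empty plasmid, and so do not decide it.

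Splits of the 6 arrays bear on the counts. The real split is counted among the 10 splits into 3 and 3. Of these, 1 gave as many genes as the real one (3835, highest other 0) and 1 as many lists (18, highest other 16). For chromosomes, 4 gave as many (2, highest other 2), of which 3 were other splits. The 10 splits are too few for a share under 0.1. Each of the other splits sets 2 arrays of one group and 1 of the other against the rest and so keeps part of the real difference, and the 7 to 16 lists and the chromosomes called in them are not independent of it. The real difference also widens the spread within each side of these splits, so the 0 genes called in them are no evidence either.

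The next pattern is the lower level of chromosomes I and II. Tests argue against coding length and expression level as its source: over 10000 gene sets from other chromosomes matched on both, the permutation p was 1e-04 for chromosome I and 1e-04 for chromosome II, the smallest they can give, with lowest medians of -0.26 and -0.17 among the sets. A chromosome-wide difference in copy number may underlie it. The lower level was spread along both chromosomes: 100% of the windows of 10 neighbouring genes on chromosome I and 94.4% on chromosome II lay below the genome's median, against 25% to 55.6% on the others (values with the length trend removed, genes with a mean log2 level over 6). Window medians ran from -0.50 to -0.10 on chromosome I and from -0.46 to 0.26 on chromosome II. Both chromosomes were picked for their low medians, so low windows follow in part from that choice and do not test copy number. For a change in every cell, the log2 value is -1 from 2 copies to 1, -0.585 from 3 to 2 and -0.415 from 4 to 3; the medians were -0.44 and -0.32 against -0.071 and -0.065 for the rest of the genome, and -0.38 and -0.24 with the length trend removed. Ploidy and DNA content are not given in the labels, and why independent colonies would share such a difference was not tested.

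The last pattern is RTP1, whose log2 difference of 2.52 compares with 2.08 for the next of the genes longer than 1200 nt. The length trend does not account for the rise, which was 2.78 after its removal, nor does a change of its neighbourhood, since the 6 nearest measured genes had a median of -0.22. A hypothesis is that the yEVenus plasmid could carry the end of RTP1 with the sequence upstream of its neighbour HSC82, as a promoter fragment would. HSC82 itself was at -0.20, and 0 measured genes lie between them, so this cannot be told apart from a rise of the chromosomal gene without the plasmid's sequence, which was not used here.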

How the results depend on the processing

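The length-trend and chromosome settings were chosen after seeing the data; the other 21 of 24 were planned. Under cyclic loess, median centring, quantile normalization and the remaining settings not named here, the counts of changed, higher and lower genes stayed within 1.5 times, although falls no longer clearly outnumbered rises under median centring (1846 higher, 1858 lower) and cyclic loess (1787 and 1897). Against 1.2-fold, 1753 genes changed, 846 higher and 907 lower, as a stricter test must give fewer. Lists past the threshold numbered 11 at an adjusted p under 0.01, 0 with an estimated correlation, 37 with fry, 11 with the length trend removed and 11 with chromosomes I and II left out too. With an estimated correlation 0 chromosomes passed, at unchanged medians of -0.44 for I (adjusted p = 0.246) and -0.32 for II (0.303), where larger correlations widen the test. SSE1, near background, was at -0.081 under cyclic loess, -0.046 under quantile normalization and 0.23 with the length trend removed (adjusted p = 0.0199, and 0.0201 without chromosomes I and II), so the removal shifts a deleted gene near background past the threshold.

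With the length trend removed, results that turned in direction were histones (-0.21), cytosolic ribosomal proteins (-0.031), HTB1 (-0.088), HHT2 (-0.21) and HSP10 (-0.13), and, not past the threshold in either setting, trehalose and glycogen (0.060), ergosterol (0.0021), inositol and phospholipid (0.043), G1 and S phase (0.14) and multidrug resistance (0.012). With chromosomes I and II left out as well, these were histones -0.088, cytosolic ribosomal proteins -0.027, HTB1 -0.088, HHT2 -0.21, HSP10 -0.13, trehalose and glycogen 0.088, inositol and phospholipid 0.043, G1 and S phase 0.23, multidrug resistance 0.012 and ubiquitin and protein quality control 0.070. The test of lists far from the threshold also turned for the unfolded protein response (-0.018 under cyclic loess, -0.051 under quantile normalization, -0.049 without the dimmest genes), G1 and S phase (0.084, 0.039 and -0.021 in the same order, 0.077 with median centring, 0.047 without chromosomes I and II, -0.059 to 0.052 when an array was left out) and phosphate starvation (-0.11 without the dimmest genes). The cause was not tested.

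Leaving out 1 array at a time gave 3359 to 3809 changed genes (1420 to 1614 higher, 1939 to 2195 lower), 16 to 19 lists, 2 chromosomes, medians of -0.45 to -0.39 for I and -0.33 to -0.31 for II, LEU2 at -0.87 to -0.84 and SSE1 at -0.038 to 0.076. Chromosomes were tested only under median centring, with an estimated correlation, with the length trend removed and with each array left out. The totals that follow count the same lists and genes once per setting. Most named genes were chosen for large differences or small p, so that they keep the call was likely from the start. Over all settings, 762 list results and 1681 named-gene results kept their direction and side of the threshold, 58 and 2 lost the call in the same direction, 34 and 2 gained it and 26 and 10 changed direction. Among the last, histones (adjusted p = 0.124, and 0.73 without chromosomes I and II), cytosolic ribosomal proteins (0.161 and 0.122) and HTB1 (0.113 and 0.117) also lost the call with the length trend removed. No block was used because the labels call the replicates independent colonies. Same-numbered arrays had residual correlations of 0.193, -0.129 and 0.196, too few values to decide whether the numbers pair the arrays. With the replicate block, 3827 genes changed and 19 lists passed, the iron regulon at 0.0413 being the list that differed. Without the dimmest genes, 12 lists passed, and the cause of the lost calls was not tested.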

Other observations

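The genes and families described here were chosen after their values were seen.

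Some transporter genes were higher with yEVenus; transporters were not tested as a group. Of 14 genes of the HXT family, which include members of the hexose transport list, 7 rose and 0 fell. Among the 7 is HXT13, whose levels of 3.04 and 3.41 lay near the 3.03 and 3.19 of probe sets with no target. HXT11 rose 3.15-fold, from 5.56 ± 0.216 to 7.21 ± 0.175 (SD, n = 3 each), and HXT9 2.83-fold, with SDs of 0.126 and 0.097 (n = 3 each), while HXT14 and HXT15 stayed near 3 in both groups. Whether probe sets of the HXT and COS families read more than 1 member was not tested. With the length trend removed, 12 of the 14 rose and 0 fell, and HXT14 and HXT15, near background, were among the 12. The S-methylmethionine permease gene MMP1 rose 3.13-fold, the low-affinity iron transporter gene FET4 2.64-fold, the methionine permease gene MUP3 2.39-fold, the peptide transporter gene OPT1 2.12-fold and the phosphate transporter gene PHO89 2.07-fold. The adjusted p of HXT11, HXT9 and the genes from MMP1 to PHO89 in limma was at most 5.17e-05 (MUP3). FIG1 rose 3.10-fold and PRM5 2.69-fold, while their list, haploid-specific and pheromone genes, did not pass in camera (adjusted p = 0.251). TIR3 rose 2.03-fold, while its list, cell wall, did not pass (adjusted p = 0.341). The yapsin gene YPS6 rose 2.50-fold. In the subtelomeric COS family, 5 of 9 genes rose and 1 fell, with COS12 at 2.06-fold.

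The seripauperin family shows how far the length trend reaches. Of 13 PAU genes, which are short and alike in sequence, 7 rose and 2 fell on the deposited values (median 0.20), and 0 rose and 10 fell with the length trend removed (median -0.32). Of the 190 genes that rose 2-fold or more, 64.7% had a coding length up to 600 nt, against 16.7% of all genes.

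Marker genes describe the strain. URA3 was at 3.00 ± 0.086 and 3.02 ± 0.063 and MET17, a sulfhydrylase gene of methionine synthesis, at 3.19 ± 0.126 and 3.47 ± 0.15 (empty plasmid and yEVenus, SD, n = 3 each), near the 3.03 and 3.19 of probe sets with no target. HIS3 was at 11.25 and 11.52 and LYS2 at 12.18 and 11.78. The labels give no genotype for these genes.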
